A study of Caenorhabditis elegans with 18 samples.

How the data were processed

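Total RNA of whole worms of the strain CB3474, which carries ben-1(e1880), was sequenced by the authors as paired-end reads of 100 nt in 18 libraries. The worms had been kept at 20 °C and exposed for 4 h to DMSO or to 1 of 5 benzimidazoles at 1.13 mM. Replicates are numbered 1 to 3, except for TBZ, whose libraries are numbered 2 to 4. The values are read counts per gene as deposited by the authors, whose processing notes name Subread 1.4.6 and featureCounts. The genome build, annotation release and strand setting of the counting are not given in the sources used here. The counts were checked to be whole numbers with totals that differ between libraries, so they were used as raw counts. The table holds 20395 gene identifiers, of which 19628 have a symbol, 205 share theirs with another identifier and 767 have none. Identifiers without a symbol held 0.92% of counts. Ensembl annotation release 115 was used for symbols and for membership of the mitochondrial genome, and no coordinates are given.

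Library totals ran from 57010263 to 67277284 counts, so that 1 read in the smallest library is 0.018 CPM. Intervals and floors derived from reads cover counting error only. A gene with no read in DMSO was given a floor of 3 counts over the group, and its fold is stated as a lower bound. Levels are CPM scaled by the TMM library factors.

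Choices of groups, tests, gene lists, the rule for named genes and the other settings to try were made before the data were examined. Genes were kept by filterByExpr with a minimum count of 10, which left 17484 genes tested and removed 2911, of which 170 had no read in any library. In R 4.3.3, edgeR 4.0.16 fitted 1 quasi-likelihood model with robust dispersion to all 18 libraries, with a mean per group and 12 residual degrees of freedom. The common biological coefficient of variation was 0.303. The spread of a gene was taken as equal in all 6 groups. Each drug was compared with DMSO, each of the 10 drug pairs was compared directly, and 1 test asked for any difference among the 6 groups. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and intervals cover 95%. The edgeR test gives no standard error (SE). The SE was approximated as the absolute log2 fold change over the square root of the F statistic, and the intervals rest on it. Because no culture or batch was named, a p-value describes the spread between libraries and not between independent experiments.

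The 36 gene lists were defined by symbol patterns and covered detoxification, stress, immunity, lipid, cuticle, reproductive, cytoskeletal, ribosomal, proteasomal and tissue marker genes. Lists with at least 3 tested members, 35 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The mitochondrially encoded list matched 1 tested gene that is not mitochondrial, so it was not tested and the share of mitochondrial genome genes was computed from the annotation. Ribosomal RNA was not analysed here. Lists overlap: all 10 cyp-35 genes are also P450 genes, and 10 glutathione S-transferases are also SKN-1 genes. An 18-gene list of early embryonic genes was written after the ABZ results were seen and is reported in the closing section.

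Named genes followed a fixed rule. For each drug it took the 10 largest rises and 5 largest falls among called genes with a group mean of at least 1 CPM and with all 3 drug libraries beyond all 3 DMSO libraries. It added up to 4 called members of each list with the largest change, all tubulins, the 3 largest differences each way for each drug pair, and any gene named under another drug.

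Likeness between drugs was described by the correlation and covariance of log2 changes and by shared calls. For comparison, 100 simulated draws took 9 library deviations at random from all groups, scaled for the loss of the group mean, and split them into 3 unchanged groups sharing 1 control group. The plan had been to keep the DMSO libraries fixed. The simulated groups had no calls in common in any draw, so they give no value to compare shared calls with, and these stand beside the overlap of independent lists only. Shares of counts were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3 libraries, and for the pairs of ABZ and DMSO libraries by exact sign flips, added after the data were seen, which cannot go below 0.25.

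The tests were tried on simulated counts with known changes, drawn with the trended dispersion. Of the genes edgeR called, 3.1% to 8.9% were false. The limit set for false calls was at first applied to DESeq2 1.42.0 as well, which missed it with 22.5% to 29.9%. It was then kept for edgeR alone, after those values had been seen. Among 16281 unchanged genes DESeq2 gave p under 0.001 in 0.36% and edgeR in 0.061%, where 0.1% is the nominal share. Of 35 lists camera called 2, the changed cyp-35 list and the P450 list that contains it. The simulated genes were drawn independently, so this does not test the preset correlation.

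Replicate numbers were taken as pairing 2 groups only if the groups shared 3 numbers and the deviations of every same-numbered pair of libraries correlated above 0.1, a limit chosen when the counts were analysed. This held for ABZ and DMSO alone (0.73, 0.84 and 0.57), 1 of 10 group pairs with 3 shared numbers. MBZ and TBZ, which share 2 numbers and so were not counted, gave 0.31 and 0.44, and 12 of 18 libraries correlated best with a library of their own number, so structure by number beyond ABZ and DMSO is not excluded. The other settings were DESeq2 size factors, no filter, a filter of 5 CPM in 3 libraries, the DESeq2 test, the replicate number as a block, a fit of the 2 compared groups only, counts thinned to the smallest library, a 2-fold minimum, an estimated correlation, and leaving out each library in turn. After the data were seen, 3 more were added: a block within ABZ and DMSO alone, leaving out both libraries numbered 2 of DMSO and ABZ, and the sperm-gene level of each library as a covariate, which removes the change of the sperm genes themselves by construction.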

Results

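Transcript levels were measured by RNA sequencing in whole Caenorhabditis elegans of the strain CB3474, which carries the e1880 allele of ben-1, the beta-tubulin gene through which benzimidazole anthelmintics act on wild-type worms. Animals were exposed for 4 h to albendazole (ABZ), fenbendazole (FBZ), oxfendazole (OxBZ), mebendazole (MBZ) or thiabendazole (TBZ), each at 1.13 mM in DMSO, or to DMSO alone. Each of the 6 groups had 3 libraries, 18 in all, with 57010263 to 67277284 counted reads per library, so that 1 read in the smallest library corresponded to 0.018 CPM, counts relative to the scaled library total. The protocol describes worms grown from the first larval stage for about 70 h to adulthood, whereas the source label describes a mixture of larval stages, and the labels were not reconciled here. The labels call the libraries biological replicates without saying whether each drug had its own cultures, so p-values measure only the spread between these libraries. The comparisons ask which transcripts differ after each drug in this strain, and whether structurally related drugs differ at matched dose and time. Group levels are given as mean CPM ± SD (n = 3), and changes as edgeR log2 fold changes ± an approximate SE derived from the F statistic.

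Libraries of the same group did not spread equally. The first principal component held 47.3% of the variance and placed the 3 FBZ libraries at 117.9 to 125.6, DMSO replicate 2 at -135.6 and ABZ replicate 2 at -122.3. The second component held 19.8% and set the OxBZ libraries, at -104.7 to -87.2, apart from all others. Transcripts of sperm genes took 0.225% ± 0.207 of counts in DMSO, 0.206% ± 0.21 in ABZ and 0.0238% ± 0.00132 in FBZ. Within DMSO and ABZ the sperm share was highest in replicate 2, at 0.462% and 0.447%. Exact two-sided permutation tests of this share against DMSO gave p = 0.1 for FBZ, the smallest value that 3 against 3 libraries allow, and 0.3 to 0.7 for the other drugs, all at least 0.4 after adjustment. Shares of counts in vitellogenins, collagens, ribosomal protein genes, mitochondrial genome genes and the 10 most abundant genes also gave adjusted exact permutation p of at least 0.4 for every drug. With a floor of 0.1 none could pass, so this does not show equal composition. Unadjusted p was at that floor, with all drug libraries below all DMSO libraries, for 3 of these shares. They were collagens under FBZ, OxBZ and TBZ, mitochondrial genome genes under OxBZ and MBZ, and ribosomal protein genes under FBZ. The permutation tests leave out the pairing of ABZ and DMSO libraries by number. Within the 3 pairs the share was lower under ABZ in 3 of 3 for collagens (-0.434, -0.89 and -0.833 percentage points), vitellogenins, sperm genes, mitochondrial genome genes and the 10 most abundant genes, and in 2 of 3 for ribosomal protein genes. Exact sign flips gave p = 0.25 for each of the first 5, the smallest value that 3 pairs allow, and p = 0.5 for the last.

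**Figure D1:**
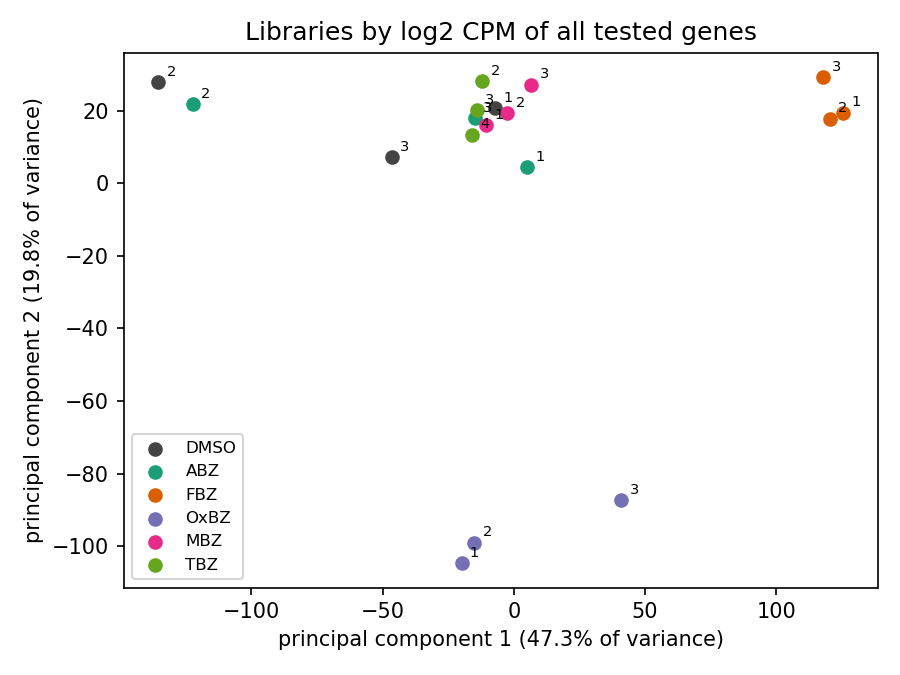
Each point is 1 library placed by its first (x axis) and second (y axis) principal component of log2 CPM over all tested genes, coloured by group and marked with its replicate number. The FBZ libraries lie at 117.9 to 125.6 on the first component, and the replicate 2 libraries of DMSO and ABZ lie at -135.6 and -122.3.

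The tubulin gene mutated in this strain was examined first. The level of ben-1 (WBGene00000248) was 57.7 ± 7.81 CPM in DMSO and between 52 and 66.4 CPM under the drugs. Its log2 fold change was 0.04, 0.2, -0.1, -0.15 and -0.07 for ABZ, FBZ, OxBZ, MBZ and TBZ, and no drug passed the threshold. Reads assigned to the gene do not show the state of the e1880 allele. Among the 16 tubulin genes, tbb-6, a divergent beta-tubulin, rose from 3.55 ± 2.02 CPM in DMSO to 105 ± 8.46 under OxBZ, 39.1 ± 8.03 under FBZ and 18.8 ± 15.5 under ABZ. The log2 changes of tbb-6 were 4.88 ± 0.56, 3.46 ± 0.53 and 2.41 ± 0.51. Under MBZ (2.06) and TBZ (0.99) tbb-6 did not pass. The alpha-tubulin gene tba-7 rose under OxBZ by 1.41 ± 0.37 and fell by 1.53 under TBZ. The abundant tubulin genes tbb-1, tbb-2 and tba-1 rose under OxBZ by 0.55, 0.52 and 0.52. In total 7 tubulin genes rose and 2 fell under FBZ and likewise under OxBZ, 1 rose under ABZ, none passed under MBZ and 1 fell under TBZ. The tubulin list as a whole passed under no drug (adjusted p of 0.07 or more, camera).

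**Figure D2:**
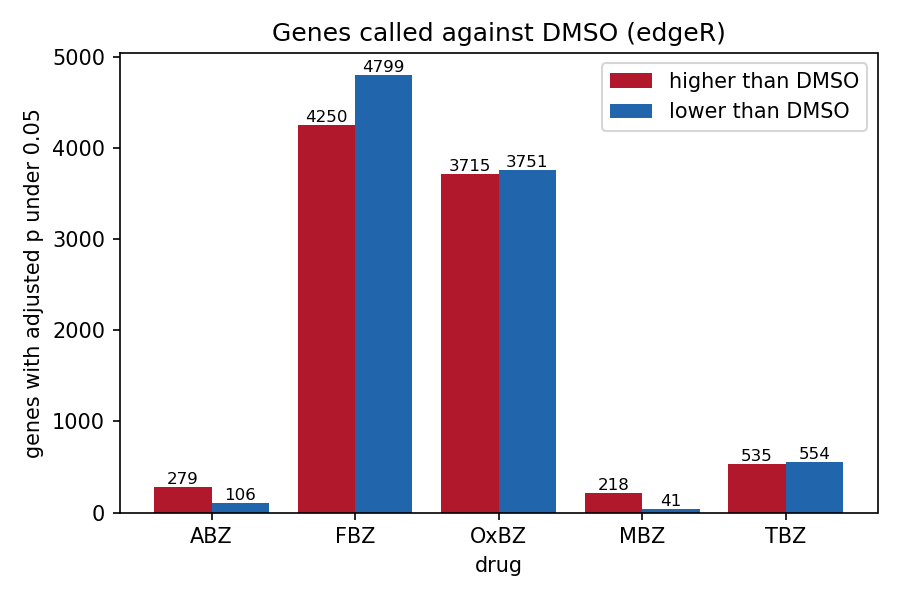
Bars give the number of genes (y axis) higher or lower than DMSO at an adjusted p under 0.05 for each drug (x axis), from 1 edgeR fit of all 18 libraries. FBZ has 4250 higher and 4799 lower genes, and MBZ has 218 and 41.

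Albendazole, a benzimidazole carbamate with a propylthio side chain, had genes of xenobiotic metabolism among its largest rises. The 10 genes with the largest rise included 5 cyp-35 genes, cytochrome P450s known for induction by foreign compounds. The transcript of cyp-35C1 went from 7.75 ± 2.54 to 1130 ± 76.4 CPM, a log2 change of 7.19 ± 0.42 (adjusted p = 1.89e-07). That of cyp-35A1 rose by 8.35 ± 0.41 from 0.0798 CPM, of cyp-35A5 by 7.13 ± 0.37 and of cyp-35D1 by 6.27 ± 0.26. In total 279 genes were higher and 106 lower than in DMSO among 17484 tested.

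Of the 10 cyp-35 genes 8 rose under ABZ and none fell, 9 and 1 when adjusted over the list alone, with a list median of 5.74 (camera adjusted p = 7.1e-27). Across all 74 cytochrome P450 genes 20 rose and 1 fell, with 27 and 1 adjusted over the list alone. Of 66 UDP-glucuronosyltransferases, enzymes that conjugate lipophilic compounds to sugars, 23 rose and 1 fell, with 27 and 3 adjusted over the list alone. The largest was ugt-67 at 5.77 ± 0.55, while ugt-8 went from 2.15 ± 0.4 to 84 ± 13.2 CPM and ugt-9 rose by 4.37 ± 0.29. The P450, cyp-35 and glucuronosyltransferase lists also passed with an estimated correlation (adjusted p = 0.0063, 0.0013 and 0.00046). Only 2 of 47 glutathione S-transferase genes rose, gst-5 by 2.23 ± 0.26 and gst-21 by 1.73 ± 0.17, and gst-29 fell by 1.88. That list did not pass (adjusted p = 0.52, camera). Among other oxidoreductases and esterases 7 rose and 2 fell, including the carboxylesterase genes cest-33 (2.37 ± 0.11) and cest-35.2 (3.04 ± 0.21), without a call for the list (adjusted p = 0.11, camera). Of 224 nuclear hormone receptor genes 15 rose and 2 fell, with nhr-178 at 2.39 ± 0.32 and nhr-205 at 1.86 ± 0.25, and 22 and 3 adjusted over the list alone. That list's call was lost with the other setting (adjusted p = 2.9e-05, then adjusted p = 0.2 with an estimated correlation).

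Outside detoxification, 3 of 12 metal response genes rose under ABZ, 5 adjusted over the list alone, among them cdr-1, a cadmium-responsive gene, at 4.31 ± 0.32 and the metallothionein gene mtl-2 at 1.11 ± 0.25. The list passed in both settings (adjusted p = 0.00026, and adjusted p = 0.03 with an estimated correlation). The lectin gene clec-206 rose by 6.44 ± 0.58, although only 2 of 187 C-type lectin and lysozyme genes rose and 1 fell. Immune genes irg-4, irg-5 and irg-6 rose by 3.95 ± 0.81, 4.82 ± 1.01 and 3.91 ± 0.89 with wide spread between libraries (irg-4 299 ± 198 CPM). The innate immunity list, with 8 of 110 higher and 2 lower, did not pass (adjusted p = 0.52, camera). In fatty acid metabolism 3 of 94 genes fell and none rose, with 5 lower adjusted over the list alone: elo-6, a fatty acid elongase gene, was at -1.13 ± 0.26, ech-6 at -0.69 ± 0.14 and elo-1 at -0.41 ± 0.09. The list median was -0.09 (adjusted p = 4e-05, and adjusted p = 0.0063 with an estimated correlation). The largest falls included wee-1.1, sdz-18 and ceh-51, genes transcribed in early embryos, at -2.52 ± 0.41, -2.48 ± 0.48 and -2.45 ± 0.54, from 1.26 ± 0.481, 1.45 ± 0.704 and 1.09 ± 0.498 CPM in DMSO. Collagens had a median of -0.41 with 1 of 167 lower, col-153, and the list call was lost (adjusted p = 0.00012, then adjusted p = 0.77 with an estimated correlation). The collagen median was 0.35 without DMSO replicate 2 alone, which leaves its paired ABZ library in, and -0.36 without both libraries numbered 2. Within the pairs the mean collagen level, on a log2 scale relative to the DMSO mean, was lower under ABZ in 3 of 3 (-0.48 against -0.16, 0.31 against 0.77 and -0.66 against -0.61). None of 80 sperm genes and none of 6 vitellogenins passed.

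The number of ABZ calls depended on how the spread was estimated. With only ABZ and DMSO libraries in the fit 26 genes were higher and 1 lower, with the replicate number as a block in those libraries 317 and 239, and without ABZ replicate 2 149 and 22. The block within ABZ and DMSO ended the call of 3 genes named in the text and of 1 list. With it 30 named genes and 10 lists stayed as they were.

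Fenbendazole, a carbamate with a phenylthio side chain, gave 4250 genes higher and 4799 lower than DMSO, 51.8% of those tested. The P450 gene cyp-35A3 went from 0.182 ± 0.231 to 34.2 ± 6.01 CPM, a log2 change of 7.58 ± 0.83, cyp-35A1 rose by 7.28 ± 0.4 and gba-2, a glucocerebrosidase family gene, by 7.13 ± 0.54 to 142 ± 18.7 CPM. The heat shock gene hsp-16.2 went from 0.37 ± 0.208 to 20.5 ± 4.49 CPM. Sperm genes were lower in 76 of 80 cases. The transcript of E02C12.10, supported by 6 reads in DMSO, reached 84.8 ± 7.6 CPM.

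Under FBZ 9 of 10 cyp-35 genes rose and all 10 did when adjusted over the list alone, with a median of 5.19. The list call was lost with the other setting (adjusted p = 2.4e-07, then adjusted p = 0.091 with an estimated correlation). Of 74 P450 genes 45 rose and 6 fell, 50 and 7 adjusted over the list alone, and of 66 glucuronosyltransferases 34 rose and 8 fell, 34 and 10 adjusted over the list alone. Both calls were lost in the same way (adjusted p = 6e-09 and 0.00025, and adjusted p = 0.091 for each with an estimated correlation). The genes ugt-67, ugt-34 and ugt-33 rose by 6.94 ± 0.56, 5.62 ± 0.49 and 5.5 ± 0.4. Nuclear hormone receptor genes were higher in 111 of 224 cases and lower in 17, with 18 lower adjusted over the list alone (adjusted p = 6.4e-08, then adjusted p = 0.091 with an estimated correlation). Among oxidoreductases and esterases 24 rose and 12 fell, led by cest-35.2 at 5.44 ± 0.23 and the flavin monooxygenase gene fmo-5 at 3.42 ± 0.35 (adjusted p = 0.025, then adjusted p = 0.36 with an estimated correlation). Glutathione S-transferases went both ways, 16 higher and 7 lower of 47, with gst-5 at 3.14 ± 0.27 and gst-8 at 5.03 ± 0.76, and short-chain dehydrogenases likewise, 10 higher and 8 lower of 30, with dhs-14 at 2.15 ± 0.24. ABC transporters were higher in 12 and lower in 20 of 52 cases. None of these last 3 lists passed (adjusted p of 0.2, 0.73 and 0.73, camera).

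Of 15 heat shock genes 6 rose and 1 fell under FBZ. Among them hsp-16.41 rose by 5.97 ± 1.02, hsp-16.2 by 5.78 ± 0.66 and the inducible chaperone gene hsp-70 by 4.73 ± 0.75. The list did not pass (adjusted p = 0.12, camera). Metal response genes were higher in 6 and lower in 2 of 12 cases, with cdr-1 at 5.31 ± 0.32 (adjusted p = 0.09, camera). The endoplasmic reticulum and mitochondrial unfolded protein response lists did not pass (adjusted p = 0.9 and 0.56, camera), with hsp-4, a marker of the former, falling by 0.55. Of 35 intracellular pathogen response genes 20 fell and 2 rose, 21 and 2 adjusted over the list alone, with pals-39 at -3.2 ± 0.38 and pals-37 at -3.04 ± 0.41 (adjusted p = 4e-04, then adjusted p = 0.41 with an estimated correlation). Immune genes otherwise went both ways, 22 higher and 23 lower of 110, with irg-4 at 3.9 ± 0.81 and irg-6 at 5.92 ± 0.96.

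The sperm genes of FBZ had a median log2 change of -4.89, among them msp-64, a major sperm protein gene, at -5.54 ± 0.9 and msd-2 at -5.5 ± 0.93. Adjusted over the list alone 77 fell and 1 rose (adjusted p = 9e-15, then adjusted p = 0.45 with an estimated correlation). Their level in DMSO differed widely between libraries (msp-64 34.3 ± 35.6 CPM), while the sperm level of the FBZ libraries lay at -3.78 to -3.36 on a log2 scale relative to the DMSO mean. Other reproductive lists moved less: 16 of 22 oocyte and eggshell genes fell with a median of -0.31, and 26 of 28 germline genes with a median of -0.36 (adjusted p = 0.45 and 0.2 with an estimated correlation). Germline examples were gld-1 at -0.52 ± 0.1 and glp-1 at -0.51 ± 0.09. Molting and hedgehog-related genes rose in 32 of 62 cases and fell in 2, with a median of 1.21, for instance grd-13 at 3.86 ± 0.69 (adjusted p = 1.5e-05, then adjusted p = 0.34 with an estimated correlation). Collagens split into 43 higher and 63 lower of 167, with no call for the list (adjusted p = 0.71, camera). Of 15 neuronal markers 13 rose, including rab-3 at 1.86 ± 0.12 and eat-4 at 1.89 ± 0.22 (adjusted p = 1.2e-07, then adjusted p = 0.091 with an estimated correlation), and 7 of 14 intestinal markers fell, including asp-1 from 3640 ± 302 to 1930 ± 8.72 CPM (adjusted p = 0.016, then adjusted p = 0.091 with an estimated correlation). Neuropeptide and insulin genes rose in 35 and fell in 11 of 134 cases, 28 and 11 adjusted over the list alone, with nlp-39 at 3.42 ± 0.35 (adjusted p = 0.016, then adjusted p = 0.74 with an estimated correlation). Ribosomal protein genes were lower in 71 of 79 cases at a median of only -0.25, and proteasome genes in 19 of 33 at -0.19 (adjusted p = 0.45 and 0.59 with an estimated correlation).

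The FBZ counts stayed within 1.5 times when any 1 library was left out. With the sperm-gene level of each library as a covariate, added after the data were seen, 1851 genes were higher and 2262 lower. The FBZ libraries, at -3.78 to -3.36, lay below all others on that level, the next being OxBZ replicate 3 at -2.21. The covariate thus extrapolates to FBZ, and the remaining calls cannot be read as a drug effect freed of that level. In the main fit, requiring at least a 2-fold change left 2674 and 1948.

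Oxfendazole is the sulfoxide of fenbendazole. It gave 3715 genes higher and 3751 lower than DMSO, of which 574 and 2482 changed at least 2-fold. The largest rise was again that of E02C12.10, to 538 ± 47.3 CPM, followed by cyp-35A1 at 9.37 ± 0.42 and ugt-33, which went from 0.297 ± 0.153 to 180 ± 20.8 CPM (9.25 ± 0.45, adjusted p = 6.94e-09). C-type lectin and lysozyme genes fell in 95 of 187 cases, clec-70 from 102 ± 75.7 to 0.683 ± 0.162 CPM. All but 1 of the 33 proteasome genes rose, by a median of 0.52.

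Of 74 P450 genes 53 rose and 4 fell under OxBZ, 55 and 5 adjusted over the list alone, with cyp-35A3 at 8.39 ± 0.85 and cyp-14A4 at 8.07 ± 0.54. Of 10 cyp-35 genes 9 rose, also when adjusted over the list alone, and of 66 glucuronosyltransferases 32 rose and 10 fell, 32 and 11 adjusted over the list alone, with ugt-9 at 6.93 ± 0.32. These 3 lists passed in both settings (adjusted p = 0.0061, 0.042 and 0.042 with an estimated correlation). Glutathione S-transferases split evenly, 11 higher and 11 lower of 47, with gst-33 at 7.16 ± 0.74 and gst-21 at 5.88 ± 0.2 (adjusted p = 0.82, camera). The short-chain dehydrogenase gene dhs-23 rose from 1.34 ± 1.23 to 392 ± 53.8 CPM, and 9 of 30 genes of its list rose and 3 fell (adjusted p = 0.22, camera). Among oxidoreductases and esterases 16 rose and 15 fell, cest-33 by 4.08 ± 0.12 upward, while the flavin monooxygenase gene fmo-2 fell by 3.94 (adjusted p = 0.68, camera). The P-glycoprotein gene pgp-9 rose from 14.1 ± 10 to 595 ± 83.4 CPM and pgp-5 by 2.69 ± 0.34, within a transporter list of 15 higher and 14 lower that did not pass (adjusted p = 0.52, camera). Nuclear hormone receptors were balanced, 34 higher and 37 lower of 224, with nhr-99 at -3.2 ± 0.23 and nhr-237 at 3.07 ± 0.22 (adjusted p = 0.98, camera).

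Lectin genes had a median of -1.24 under OxBZ, with 9 higher and 95 lower, or 10 and 100 adjusted over the list alone, and clec-206 among the exceptions at 7.4 ± 0.59. The lectin list passed in both settings (adjusted p = 1.1e-09, and adjusted p = 6.1e-05 with an estimated correlation), as did the intestinal markers, of which 10 of 14 fell and 1 rose (adjusted p = 9e-05, and adjusted p = 0.013 with an estimated correlation). Among the intestinal genes the peptide transporter gene pept-1 was at -2.83 ± 0.42, the ferritin gene ftn-1 at -2.85 ± 0.33 and the intermediate filament gene ifb-2 at -1.94 ± 0.29. Lysosomal lipase genes lipl-3 and lipl-1 fell, at -5 ± 0.33 and -3.92 ± 0.4, within a fatty acid list of 17 higher and 39 lower of 94 (adjusted p = 0.0099, then adjusted p = 0.089 with an estimated correlation). Of 21 fasting and daf-16 target genes 9 fell and 3 rose, with dod-22 at -5.05 ± 0.38 (adjusted p = 0.047, then adjusted p = 0.32 with an estimated correlation). Innate immune genes rose in 18 and fell in 29 of 110 cases, irg-2 by 6.22 ± 0.44 upward (adjusted p = 0.31, camera), and pathogen response genes fell in 18 of 35 cases and rose in 3, with pals-29 at -2.95 ± 0.5 (adjusted p = 0.0097, then adjusted p = 0.52 with an estimated correlation). Metal response genes were higher in 5 and lower in 1 of 12 cases, with cdr-1 at 8.24 ± 0.34 (adjusted p = 0.031, then adjusted p = 0.22 with an estimated correlation). SKN-1 oxidative stress genes rose in 7 of 20 cases and fell in 1, gst-5 by 4.4 ± 0.28 (adjusted p = 0.04, then adjusted p = 0.6 with an estimated correlation).

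Proteasome genes pbs-2 and rpn-10 rose by 0.78 ± 0.06 and 0.6 ± 0.06 under OxBZ (list adjusted p = 4.5e-18, then adjusted p = 0.22 with an estimated correlation). Heat shock genes rose in 7 and fell in 2 of 15 cases, the abundant chaperone genes hsp-1 and hsp-90 by 0.57 ± 0.11 and 0.45 ± 0.08 (adjusted p = 0.0099, then adjusted p = 0.089 with an estimated correlation). The unfolded protein response of the endoplasmic reticulum had 5 higher of 17 genes (adjusted p = 0.16, camera) and that of mitochondria 5 higher of 11, dve-1 by 0.72 ± 0.12 (adjusted p = 0.041, then adjusted p = 0.52 with an estimated correlation). Neuropeptide and insulin genes fell in 84 of 134 cases and rose in 1, and neuronal markers in 10 of 15 with 1 higher, with egl-3 at -0.91 ± 0.14 and egl-21 at -0.96 ± 0.13 (adjusted p = 0.21 and 0.22 with an estimated correlation). Muscle markers fell in 10 of 18 cases, with the myosin gene myo-3 at -0.8 ± 0.2 (adjusted p = 0.0013, then adjusted p = 0.52 with an estimated correlation). Sperm genes fell in 36 of 80 cases and rose in 2, or 61 and 2 adjusted over the list alone. Their median was -1.88 (camera adjusted p = 2.8e-06, then adjusted p = 0.6 with an estimated correlation). The sperm level of OxBZ replicates 1, 2 and 3 lay at -1.07, -1.11 and -2.21 on the same scale. That of DMSO replicates 1, 2 and 3 lay at -1.1, 1.49 and -0.4, so only OxBZ replicate 3 was clearly below all DMSO libraries. Collagens fell in 35 of 167 cases, 27 adjusted over the list alone, with none higher (adjusted p = 4.2e-05, then adjusted p = 0.52 with an estimated correlation). Without DMSO replicate 2 the collagen list was not called. Germline genes rose in 14 and oocyte genes in 9 cases, mcm-7 by 0.45 ± 0.07 and pie-1 by 0.46 ± 0.08 (adjusted p = 0.36 and 0.6 with an estimated correlation). Kinesins and dyneins rose in 18 of 40 cases and fell in 5, with a median of 0.21 but a mean of -0.08 while the test gave a rise (adjusted p = 0.029, then adjusted p = 0.34 with an estimated correlation). Ribosomal protein genes had a median of 0.08 with 7 higher and 2 lower, or 2 and 2 adjusted over the list alone (adjusted p = 0.025, then adjusted p = 0.8 with an estimated correlation). This median of ribosomal proteins for OxBZ against DMSO turned to -0.02 with a filter of 5 CPM, -0.04 without DMSO replicate 1 and -0.01 without OxBZ replicate 1.

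Of the OxBZ counts, genes higher numbered 1921 without OxBZ replicate 1, 2203 without DMSO replicate 2 and 2241 without DMSO replicate 1. Genes lower numbered 1911 with only OxBZ and DMSO libraries in the fit, 2397 without OxBZ replicate 2 and 2500 without OxBZ replicate 1.

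Mebendazole, which carries a benzoyl group in place of the thioether, gave 218 genes higher and 41 lower than DMSO. The largest rise was that of cyp-13A6, a cytochrome P450 gene, from 0.69 ± 0.119 to 441 ± 58.3 CPM (9.31 ± 0.61, adjusted p = 5.68e-07). The next was cdr-1, from 0.483 ± 0.141 to 220 ± 24.6 CPM. K12D9.1, cyp-35A1, clec-206 and cyp-35A5 followed at 7.09 ± 0.94, 6.57 ± 0.39, 5.92 ± 0.57 and 5.91 ± 0.35. The largest fall was that of C30G12.2, at -2.26 ± 0.47.

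Of 74 P450 genes 26 rose and none fell under MBZ, 39 and 2 adjusted over the list alone, and of 10 cyp-35 genes 8 rose, 9 adjusted over the list alone, with cyp-35C1 at 5.64 ± 0.39. Of 66 glucuronosyltransferases 23 rose and none fell, 27 and 2 adjusted over the list alone: ugt-16 went from 6.67 ± 5.28 to 130 ± 28.4 CPM and ugt-61 from 10.3 ± 1.43 to 134 ± 15.3. These 3 lists passed in both settings (adjusted p = 0.0012, 0.0085 and 0.00029 with an estimated correlation). Other detoxification genes that rose were gst-33 at 3 ± 0.64, gst-5 at 2.18 ± 0.26, cest-35.2 at 4.34 ± 0.22, cest-33 at 2.79 ± 0.12, dhs-14 at 1.53 ± 0.23, pgp-9 at 4.08 ± 0.52 and haf-7 at 1.21 ± 0.18. The glutathione S-transferase list, with 4 of 47 higher, did not pass (adjusted p = 0.23, camera), and nuclear hormone receptors, with 11 higher and 1 lower of 224, lost their call (adjusted p = 1e-07, then adjusted p = 0.11 with an estimated correlation). Of the metal response genes cdr-1 alone passed (list adjusted p = 0.00068, then adjusted p = 0.066 with an estimated correlation).

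Sperm genes had a median of -1.5 under MBZ with none of 80 past the threshold (adjusted p = 4.3e-10, then adjusted p = 0.68 with an estimated correlation). The sperm level of the MBZ libraries, at -0.92 to -0.84 on the log2 scale relative to the DMSO mean, lay within that of the DMSO libraries (-1.1 to 1.49). Ribosomal protein genes had a median of -0.17, with 4 lower of 79 and 35 adjusted over the list alone, rpl-5 among them at -0.4 ± 0.09 (adjusted p = 3.1e-25, then adjusted p = 0.32 with an estimated correlation). In fatty acid metabolism ech-7 and acdh-1, an acyl-CoA dehydrogenase gene, fell, at -1.05 ± 0.23 and -0.68 ± 0.15, without a call for the list (adjusted p = 0.083, camera). The regulator of the mitochondrial stress response atfs-1 rose by 0.38 ± 0.05. Collagens had a median of -0.47 with 2 lower of 167, and none adjusted over the list alone (adjusted p = 0.0016, then adjusted p = 0.77 with an estimated correlation). This collagen median was 0.02 without DMSO replicate 2. No heat shock gene passed. With only MBZ and DMSO libraries in the fit 40 genes were higher and 1 lower. Without DMSO replicate 1 the counts were 446 and 804, without MBZ replicate 1 225 and 759, without DMSO replicate 2 128 and 28, and without MBZ replicate 2 150 and 8.

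Thiabendazole, which has a thiazolyl ring and no carbamate, gave 535 genes higher and 554 lower than DMSO. The transcript of cyp-35D1 rose from 0.606 ± 0.224 to 1220 ± 66.9 CPM, a log2 change of 10.96 ± 0.3 (adjusted p = 3.6e-11), and cdr-1 from 0.483 ± 0.141 to 668 CPM, with 435, 742 and 828 in the single libraries (10.44 ± 0.37). K08D10.13, with no read in DMSO, was at least 283-fold higher, taking 3 reads over the DMSO group as the floor. The antimicrobial peptide genes cnc-6 and nlp-34 were among those that rose, with wide spread between libraries, cnc-6 to 20.7 ± 17.7 CPM and nlp-34 from 0.758 ± 0.434 to 77.2 ± 62.3. The largest fall was that of pud-3, from 168 ± 63.2 to 5.34 ± 4.29 CPM.

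Of 10 cyp-35 genes 8 rose under TBZ, also when adjusted over the list alone, cyp-35A3 by 7.79 ± 0.83 and cyp-35A5 by 7.7 ± 0.37 (adjusted p = 1.6e-11, then adjusted p = 0.083 with an estimated correlation). P450 genes overall rose in 19 and fell in 9 of 74 cases, 26 and 13 adjusted over the list alone (adjusted p = 0.027, then adjusted p = 0.65 with an estimated correlation). Glucuronosyltransferases rose in 15 and fell in 6 of 66 cases, 19 and 8 adjusted over the list alone, with ugt-67 at 7.08 ± 0.56 and ugt-8 at 4.76 ± 0.21 (adjusted p = 0.022, then adjusted p = 0.47 with an estimated correlation). Glutathione S-transferases rose in 8 and fell in 7 of 47 cases, gst-33 by 6.69 ± 0.73 upward (adjusted p = 0.81, camera). Carboxylesterase genes fell at cest-1.1 (-3.73 ± 0.38) and rose at cest-35.2 (2.19 ± 0.21). Their list had 10 higher and 12 lower of 52, or 16 and 14 adjusted over the list alone. The short-chain dehydrogenase genes dhs-23 and dhs-20 changed by 3.92 ± 0.65 and -2.06 ± 0.39. Among transporters mrp-3 and abt-4 fell, at -1.45 ± 0.24 and -1.43 ± 0.28, and mrp-2 rose by 0.81 ± 0.17. Among metal response genes mtl-2 rose from 8.79 ± 1.68 to 95.8 ± 18.1 CPM while cdr-2 fell by 1.79 (list adjusted p = 0.58, camera).

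Innate immune genes rose in 11 and fell in 9 of 110 cases under TBZ, 22 and 12 adjusted over the list alone. Among them fipr-24 was at 6.16 ± 0.86 and cnc-1 at 5.65 ± 1.15 (list adjusted p = 0.58, camera). Pathogen response genes fell in 6 of 35 cases and rose in 1, with pals-6 at -2.08 ± 0.42 (adjusted p = 4e-04, then adjusted p = 0.65 with an estimated correlation). Collagens fell in 24 of 167 cases, 35 adjusted over the list alone, and none rose, with col-93 at -2.04 ± 0.37 and col-80 from 1160 ± 350 to 300 ± 182 CPM (adjusted p = 3.7e-07, then adjusted p = 0.65 with an estimated correlation). TBZ replicate 2 stood apart from replicates 3 and 4, with mean log2 levels relative to the DMSO mean of 0.04 against -0.85 and -1.01 for collagens, 0.04 against -2.43 and -1.88 for vitellogenins and -0.12 against -0.73 and -0.64 for muscle markers. Of 14 intestinal markers 6 fell, with the intestinal actin gene act-5 at -1.53 ± 0.26 and vha-6 at -1.22 ± 0.25 (adjusted p = 0.0024, then adjusted p = 0.083 with an estimated correlation), and of 21 fasting and daf-16 target genes 5 fell (adjusted p = 0.0098, then adjusted p = 0.42 with an estimated correlation). The fatty acid desaturase gene fat-5 rose by 1.41 ± 0.29. Sperm genes had a median of -1.24 and vitellogenins of -1.2 with none past the threshold (adjusted p = 0.7 and 0.65 with an estimated correlation), and the sperm median was 0.02 without DMSO replicate 2. The male tissue genes try-5 and swm-1 rose by 1.42 ± 0.34 and 0.54 ± 0.15, and the muscle marker tnt-2 was lower at -0.55 ± 0.14 (adjusted p = 0.65 for each list with an estimated correlation). The mean level of the male tissue list, on the same log2 scale, was 0.05 in TBZ replicate 2 against 0.9 and 0.93 in replicates 3 and 4. In the DMSO libraries it ran from -0.63 to 0.77. Histone genes rose in 3 of 34 cases and no hypodermal marker passed (adjusted p = 0.19 and 0.87, camera). With only TBZ and DMSO libraries in the fit 11 genes were higher and 1 lower, and with the replicate number as a block over all libraries 255 and 233. Without TBZ replicate 2 the counts were 1008 and 1110, without TBZ replicate 3 220 and 203, without TBZ replicate 4 220 and 166, and without DMSO replicate 2 301 and 305.

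**Figure D3:**
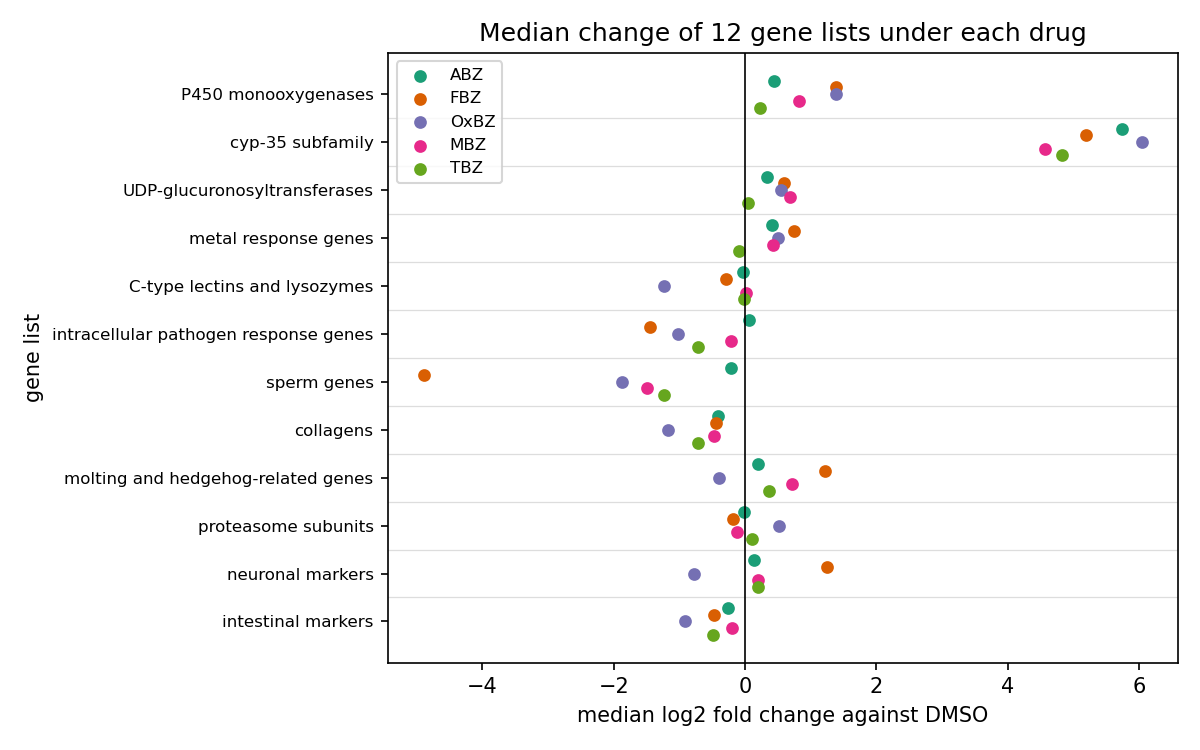
Each point is the median log2 fold change against DMSO (x axis) of 1 of 12 gene lists (y axis) under 1 drug, coloured by drug. The cyp-35 medians lie between 4.57 and 6.04 for all 5 drugs, and the sperm median is -4.89 under FBZ.

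The drugs were then compared directly at the same dose and time. ABZ and MBZ, which differ in the side chain, differed at 36 genes, whereas FBZ and its sulfoxide OxBZ differed at 10488 of 17484. MBZ and TBZ differed at 604 genes and ABZ and TBZ at 1107. FBZ differed from ABZ, MBZ and TBZ at 7459, 4710 and 6249 genes, and OxBZ from ABZ, MBZ and TBZ at 7602, 7419 and 7337. An edgeR test for any difference among the 6 groups called 12154 genes. No label names the cultures, so a difference between drugs, or from DMSO, cannot be told apart from a difference between cultures.

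Single detoxification genes separated the drugs. The level of cyp-35D1 (WBGene00008829) was 1220 ± 66.9 CPM under TBZ, 47.3 ± 4.97 under ABZ, 10.8 ± 1.35 under OxBZ, 2.57 ± 0.584 under MBZ and 0.985 ± 0.292 under FBZ. All 10 pairwise differences of cyp-35D1 passed, the smallest between FBZ and MBZ at -1.38 ± 0.24 and the largest between FBZ and TBZ at -10.27 ± 0.29. The order differed for cyp-35C1, at 1130 ± 76.4 CPM under ABZ, 335 ± 37.1 under FBZ, 364 ± 30.5 under OxBZ, 387 ± 109 under MBZ and 75.8 ± 40.2 under TBZ. For cyp-13A6 the level was 441 ± 58.3 CPM under MBZ, against 27.5 ± 0.746 under FBZ, 3.88 ± 3.03 under TBZ and 3.63 ± 1.16 under ABZ, and OxBZ lay -1.93 ± 0.43 from MBZ. For cdr-1 it was 668 CPM under TBZ and 9.56 ± 3.37 under ABZ, a difference of -6.13 ± 0.29 for ABZ against TBZ.

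**Figure D4:**
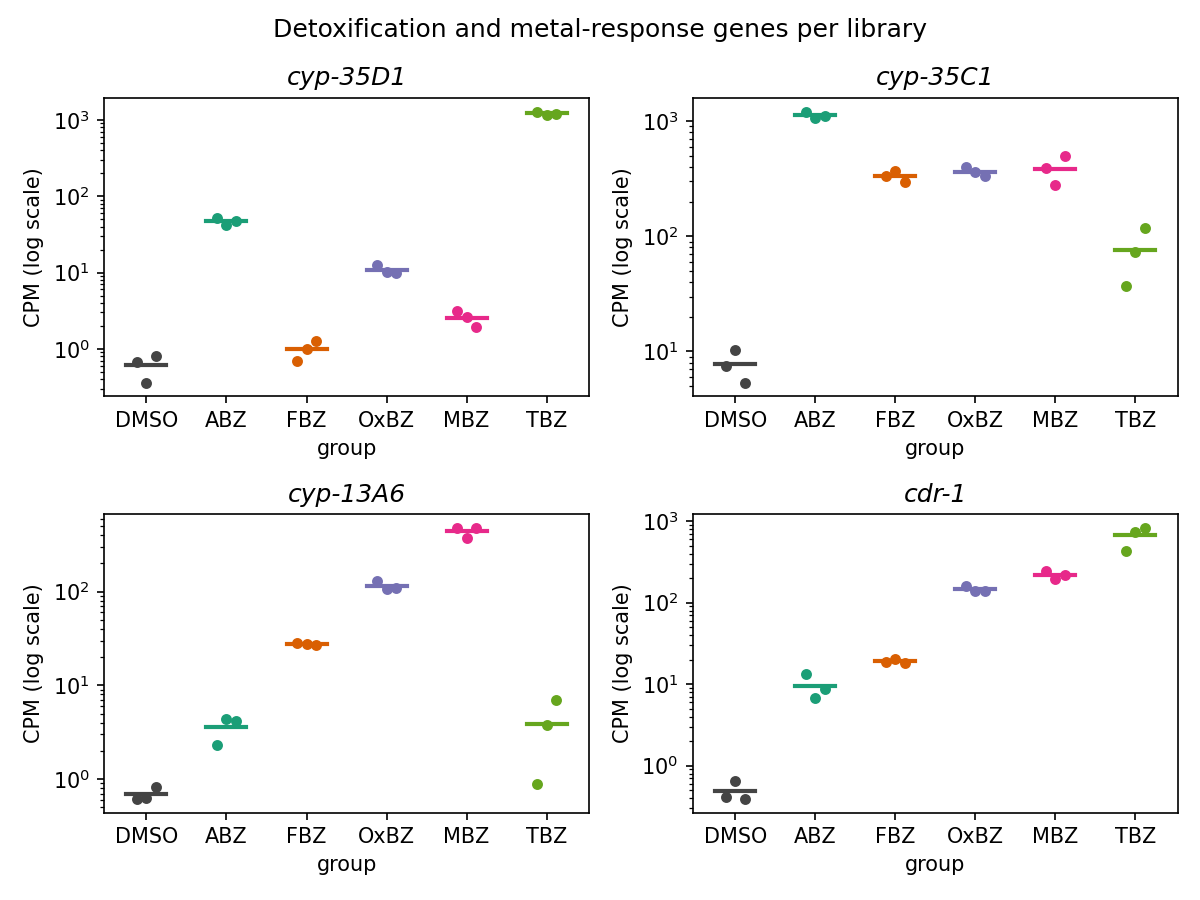
Points are single libraries (CPM, log y axis) of each group (x axis) for 4 genes, and bars mark the mean of 3 libraries. The cyp-35D1 level is 1220 CPM under TBZ and 0.985 under FBZ, while cyp-13A6 is highest under MBZ at 441 CPM.

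Between fenbendazole and its sulfoxide, the sulfide gave the lower level at ugt-33 (-3.75 ± 0.33), gst-33 (-4.24 ± 0.64), pgp-9 (-3.15 ± 0.5), cyp-13A6 (-2.07 ± 0.43) and bcmo-1 (-6.37 ± 0.36), a carotenoid cleavage enzyme gene. At cyp-35C1 the difference was -0.12 with a 95% interval of -0.8 to 0.57, and at ugt-16 0.5 with an interval of -0.27 to 1.27, so neither passed. Proteasome genes were lower under FBZ than OxBZ in 33 of 33 cases (adjusted p = 8.5e-16, then adjusted p = 0.43 with an estimated correlation). Sperm genes were lower under FBZ in 54 of 80 cases and neuronal markers higher in 14 of 15 (adjusted p = 1.4e-06 and 4.5e-08, then adjusted p = 0.7 and 0.28 with an estimated correlation). Lectin genes were higher under FBZ in 75 of 187 cases and lower in 19 (adjusted p = 0.0027, and adjusted p = 0.022 with an estimated correlation). P450 genes were lower under FBZ in 34 of 74 cases and higher in 17 (adjusted p = 0.049, then adjusted p = 0.57 with an estimated correlation), and glucuronosyltransferases lower in 23 of 66 and higher in 11, without a call (adjusted p = 0.29, camera). The heat shock genes hsp-16.2 and hsp-70 were at 20.5 ± 4.49 and 24.8 ± 4.86 CPM under FBZ and at 0.656 ± 0.125 and 2.1 ± 0.308 under OxBZ.

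Between the carbamates ABZ and MBZ, ABZ gave the higher level at cyp-35D1 (4.21 ± 0.22) and cyp-35A1 (1.78 ± 0.27) and the lower at cyp-13A6 (-6.92 ± 0.54), ugt-61 (-3.9 ± 0.12), cdr-1 (-4.53 ± 0.27) and pgp-9 (-2.87 ± 0.49). At ugt-16 the difference was -0.5 with a 95% interval of -1.27 to 0.27, and at gst-33 -1.36 with an interval of -2.62 to -0.1, and neither passed after adjustment. Between ABZ and FBZ, which differ by a propyl against a phenyl group on the sulfur, cyp-35D1 was higher under ABZ by 5.59 ± 0.25 and cyp-35C1 by 1.75 ± 0.33, cyp-13A6 lower at -2.92 ± 0.46, and ugt-16 did not pass at 0.19 with an interval of -0.58 to 0.95. Thiabendazole, without the carbamate, gave less ugt-16 than each of the others, by 3.99 ± 0.41 against ABZ and 4.49 ± 0.42 against MBZ, and less T16G1.6, by 3.47 ± 0.24 against ABZ. At cyp-13A6 and ugt-61 the differences of ABZ against TBZ did not pass, at -0.09 (95% interval -1.05 to 0.87) and -0.1 (-0.32 to 0.12), and that of cyp-13A6 had no settled direction, at -0.57 to 0.64 when 1 library was left out and 0.74 with the replicate block. P450 genes were higher under MBZ than TBZ in 26 of 74 cases and lower in 4 (adjusted p = 8.9e-12, and adjusted p = 0.032 with an estimated correlation), and higher under OxBZ than TBZ in 45 and lower in 5 (adjusted p = 0.023 with an estimated correlation).

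The count of 36 genes between ABZ and MBZ was 245 without MBZ replicate 1 and 13 without ABZ replicate 1. The count between MBZ and TBZ was 1659 without TBZ replicate 2, 277 without MBZ replicate 1, and 307 with the replicate number as a block. That between ABZ and TBZ was 44 with only those libraries in the fit and 607 without TBZ replicate 3, and that between FBZ and MBZ was 2327 without MBZ replicate 1.

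Changes common to the drugs were also counted. Under all 5 drugs 69 genes passed, 59 higher throughout, 5 lower throughout and 5 in mixed directions. The shared rises included cyp-35A1, cyp-35A3, cyp-35A5, cyp-35C1, cyp-35D1, cyp-13A6, ugt-8, ugt-9, ugt-67, gst-5, cest-33, cdr-1 and clec-206, and the shared falls C30G12.2 and cest-1.1. The receptor gene nhr-214 had no read in DMSO and was at least 33-fold higher under FBZ and at least 6.83-fold higher under OxBZ. Genes called under 1 drug alone numbered 4411 for FBZ, 2957 for OxBZ, 155 for TBZ, 25 for ABZ and 2 for MBZ, a count that does not test the difference between drugs. Across genes, which are not independent replicates, log2 changes correlated between drugs at 0.45 to 0.77, highest for FBZ and MBZ. Simulated unchanged groups sharing controls gave a mean of 0.49 (95% of draws -0.39 to 0.91), a range that holds all 10 pairs. The simulated covariance had a mean of 0.094 (-0.06 to 0.321), and of the observed covariances of 0.189 to 0.76 those of 5 of the 10 pairs lay within that range. ABZ and MBZ shared 144 higher genes against 3.48 for independent lists, which share no controls. FBZ and OxBZ shared 764 higher against 903 and 1675 lower against 1030, and 1848 genes passed in opposite directions. With 3 DMSO libraries the controls could not be split, and the part of the likeness owed to shared controls was not separated.

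Several named genes belong to families of close copies, among them the cyp-35, ugt, gst, cest, col, pals, msp and clec genes and E02C12.10, and their counts are uncertain where reads map to more than 1 copy. Strand use in the counting was not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. Because RNA came from whole worms, changes of reproductive, tissue marker, ribosomal and proteasome lists cannot be told apart from changed shares of tissues or stages.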

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

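In simulation DESeq2 called more false genes than edgeR (22.5% to 29.9% against 3.1% to 8.9%). The simulated counts used the trended dispersion estimated by edgeR, equal in all groups, so this cannot rank the tools on these libraries. The removal of both libraries numbered 2, the covariate and the ABZ and DMSO block were chosen after seeing the data. All 21 counts stayed within 1.5 times with DESeq2 size factors, with no low-count filter and with counts thinned to the smallest library, and scaling moved the median gene by at most 0.045 on the log2 scale. A 2-fold minimum left 181 and 49 genes higher and lower under ABZ, 2674 and 1948 under FBZ, 574 and 2482 under OxBZ and 328 and 209 under TBZ, and 7 lower under MBZ. For pairs it left 3683 (ABZ against FBZ), 2892 (ABZ against OxBZ), 545 (ABZ against TBZ), 4631 (FBZ against OxBZ), 2290 (FBZ against MBZ), 3019 (FBZ against TBZ), 2315 (OxBZ against MBZ), 2409 (OxBZ against TBZ) and 348 (MBZ against TBZ), fewer by construction. The DESeq2 test gave 470 and 266 for ABZ, 484 and 470 for MBZ, 931 and 1132 for TBZ, 151 for ABZ against MBZ, 1923 for ABZ against TBZ and 1045 for MBZ against TBZ. The filter of 5 CPM, which tests fewer genes, gave 3081 lower under FBZ, 127 lower under MBZ, 2451 and 2382 under OxBZ, 4642 for ABZ against FBZ and 2877 for FBZ against MBZ. With only the 2 compared groups in the fit, which has fewer residual degrees of freedom, the counts were 26 and 1 for ABZ, 40 and 1 for MBZ, 11 and 1 for TBZ, 1911 lower under OxBZ, 4663 for ABZ against OxBZ, 10 for ABZ against MBZ, 44 for ABZ against TBZ, 7423 for FBZ against MBZ and 212 for MBZ against TBZ. That fit also takes the spread from the compared groups alone, whereas the main fit takes it as equal in all 6 groups. The SD of log2 differences between libraries of a group was 0.67 to 1.18 in DMSO, 0.63 to 1.21 in ABZ and 0.36 to 0.39 in FBZ. It was 0.42 to 0.7 in OxBZ, 0.42 to 0.58 in MBZ and 0.36 to 0.7 in TBZ. In OxBZ the value was 0.42 between replicates 1 and 2, and 0.7 and 0.66 between these and replicate 3. The labels do not say whether close libraries came from separate cultures. The counts of the main fit rest on that common spread, whose part was not separated from that of the degrees of freedom. The replicate block gave 255 and 233 for TBZ, 713 for ABZ against TBZ and 307 for MBZ against TBZ, whose 2 shared numbers correlated at 0.31 and 0.44, and within ABZ and DMSO alone 239 lower. Without the libraries numbered 2 of DMSO and ABZ, 140 were higher under ABZ and 2353 under OxBZ. With the sperm covariate 246 were lower under ABZ, 1851 and 2262 higher and lower under FBZ, 811 higher under TBZ and 3311 differed for ABZ against FBZ. The FBZ sperm levels lay below those of all other libraries, so for FBZ the covariate extrapolates. Leaving out each library in turn gave, for genes higher and lower, 149 to 253 and 22 to 172 (ABZ), 3420 to 4329 and 3910 to 4945 (FBZ), 1921 to 3601 and 2397 to 4185 (OxBZ), 128 to 446 and 8 to 804 (MBZ), 220 to 1008 and 166 to 1110 (TBZ). For pairs it gave 5479 to 7103 (ABZ against FBZ), 4854 to 7465 (ABZ against OxBZ), 13 to 245 (ABZ against MBZ), 607 to 1612 (ABZ against TBZ), 8618 to 10312 (FBZ against OxBZ), 2327 to 4394 (FBZ against MBZ), 4307 to 6460 (FBZ against TBZ), 5565 to 7422 (OxBZ against MBZ), 4972 to 7392 (OxBZ against TBZ), 277 to 1659 (MBZ against TBZ), and for any difference 10666 to 12531. Where a library is left out its group keeps 2. Of the 80 list calls against DMSO 67 were lost with an estimated correlation and 13 held, and of the 135 between drugs 6 held. The other settings were run for lists against DMSO only. List directions turned in these cases: ABZ collagens at 0.35 without DMSO replicate 2 (but -0.36 for collagens in ABZ against DMSO without both libraries numbered 2), MBZ collagens at 0.02 without DMSO replicate 2 and 0.01 without both libraries numbered 2, TBZ sperm genes at 0.02 in each of these settings, OxBZ ribosomal proteins at -0.02 with the 5 CPM filter, -0.04 without DMSO replicate 1, -0.01 without OxBZ replicate 1 and at most 0.15 without any other library, and FBZ proteasome genes, whose test turned to higher at a median of -0.03, with the covariate. The value of 0.08 for sperm genes in OxBZ against DMSO with the covariate follows from its construction, since the covariate is the level of these genes, and says nothing about their stability. Among single genes named in the text, signs turned for ben-1, which passed under no drug, at 0.04 under OxBZ with the covariate, 0.04 under TBZ without both libraries numbered 2, and -0.06 to 0.15 under ABZ and -0.16 to 0.04 under TBZ when each library was left out. They also turned for cyp-13A6 for ABZ against TBZ (0.74 with the replicate block, -0.57 to 0.64 leaving out libraries), for cyp-35C1 for FBZ against OxBZ (0.02 with the 5 CPM filter, 0.08 with the covariate, -0.2 to 0.01 leaving out libraries), for ugt-16 for ABZ against FBZ (-0.92 with the covariate) and for tnt-2 under FBZ (0.09 with the covariate). The lowest medians on leaving out a library were -0.73 for ABZ collagens, -0.72 for MBZ collagens and -1.72 for sperm genes in TBZ against DMSO. Over all named genes, leaving out 1 library kept the direction and the side of the threshold in 1327 cases, lost the call in 110, gained it in 2 and turned the sign in 7. With only the 2 compared groups in the fit 165 cases stayed, 75 lost the call and 1 gained it. Without both libraries numbered 2 of DMSO and ABZ 215 stayed, 21 lost it, 4 gained it and 1 turned in sign. With the replicate block over all libraries 230 stayed, 10 lost it and 1 turned in sign. The causes were not tested beyond those given by construction.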

Other observations

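The tests of scaling, of spread between cultures, and all those of cyp-35D1 were chosen only after the results were seen, while those of the shift between libraries, of the embryonic list and of the sample splits were written before their values. Some gene groups were not described with the comparisons. Under FBZ, lipid genes split into 20 higher and 38 lower of 94, with acs-18 and acdh-8, acyl-CoA enzyme genes, at -5.51 ± 0.91 and -5.46 ± 0.94 (adjusted p = 0.18, camera). The fasting-responsive gene acs-2 rose from 89.1 ± 19.8 to 466 ± 62.1 CPM and the gluconeogenesis gene pck-1 from 331 ± 2.39 to 677 ± 25.9 CPM. Their list of fasting and daf-16 target genes had 5 higher and 4 lower of 21 and did not pass (adjusted p = 0.73, camera). The muscle genes myo-3 and tnt-4 rose by 1.15 ± 0.2 and 1.2 ± 0.31 under FBZ, while tnt-2 was at -0.55 ± 0.14. Under OxBZ the pharyngeal myosin genes myo-1 and myo-2 were at -1.58 ± 0.4 and -1.31 ± 0.33, and the immune genes irg-1 and fipr-24 rose by 4.32 ± 0.44 and 4.54 ± 0.81. Under MBZ irg-2 rose by 3.03 ± 0.38, and molting and hedgehog-related genes had a median of 0.72 with none past the threshold (adjusted p = 0.0037, then adjusted p = 0.55 with an estimated correlation).

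FBZ changed 51.8% of tested genes, in a series where DMSO and ABZ replicate 2 stood apart from their groups. The shift that parts these libraries correlated with the FBZ changes across genes at -0.68. Among 1739 genes flat along it (under 0.1 on the log2 scale in both groups) 62.8% were called under FBZ. This argues only against a shift in proportion to that one as the sole source of the calls. The FBZ libraries lay at the opposite end of the first principal component from these libraries. Genes flat between the DMSO and ABZ libraries may still differ further along that component, which the share of flat genes cannot decide. Flat genes were chosen for small differences between libraries of DMSO and ABZ. That choice also eases calls of small changes, so their share cannot be set against that of all genes. Scaling by a few abundant genes moves all genes of a library alike, and is argued against as the whole source because, whatever common shift is taken off, at least 54.1% of genes have a 95% interval that misses it; this was the 3rd test tried, after other size factors, which shifted the FBZ changes by 0, and the balance of directions, which centring sets, had been set aside as unable to decide. FBZ libraries were closer to one another than DMSO libraries (ratio of spreads 0.39), and cultures that differed for reasons other than the drug cannot be told apart from a drug effect, because the labels give no culture. A drug effect may thus be mixed with a difference between cultures.

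The level of cyp-35D1 ranged from 0.985 CPM under FBZ to 1220 under TBZ, and its ratio to the other 9 cyp-35 genes differed 2660-fold among the drugs, which excludes only a constant share of their pooled reads. An exchange of reads between copies that leaves their total unchanged is argued against for TBZ against FBZ, OxBZ and MBZ. There the other genes lost 0.299, 0.38 and 0.32 times what cyp-35D1 gained. For ABZ against these 3 drugs the other genes rose with cyp-35D1 (ratios of -23.8, -27.6 and -24). There the gains of cyp-35D1 were 46.3, 36.5 and 44.8 CPM and the losses of the others -1100, -1010 and -1080 CPM. An exchange as small as these gains could not be seen beside such rises, so these ratios cannot decide on it. The ratios assume equal true levels of the other genes under both drugs, so they cannot exclude reads of those copies counted as cyp-35D1. For TBZ against ABZ the others lost 1.25 times the gain, from 1780 to 316 CPM, which met the criterion written for an exchange, so it stays open for that pair, and among FBZ, OxBZ and MBZ gains of 1.58 to 9.84 CPM lay below the standard errors of the change in the others (46.5 to 114 CPM). Between replicate 2 and the other libraries of DMSO or ABZ, cyp-35D1 differed by a fold of at most 1.94. This argues against the shift that parts those libraries as the source, but cannot decide on a stage difference between the drug groups. A response of cyp-35D1 specific to each drug may underlie its levels, a hypothesis found and tested on the same data.

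Early embryonic genes were among the largest falls under ABZ, so an 18-gene list of others was written before its values were seen. Its 14 tested genes had a median of -0.66, with 1 called lower and 3 adjusted over the list alone (p = 2.6e-05 by camera, p = 0.12 with an estimated correlation). The ABZ and DMSO libraries of the same number differed by medians of -0.93, 0.04 and -0.52, with 14, 6 and 11 genes lower, which argues against the pair numbered 2 as the source. The bound written for this test, all 3 pairs under 0, was not met, and the verdict rests on that pair itself being at 0.04. Fewer early embryos in the ABZ cultures, or lower embryonic transcription, may underlie the value of -0.66, while medians under FBZ, OxBZ, MBZ and TBZ were 0.31, 0.26, -0.08 and 0.68, a difference between drugs that was not tested.

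Other splits of the same libraries were counted. The 10 splits of 6 libraries cannot give a share under 0.05, for any comparison of 2 groups. For ABZ against DMSO 3 of the 10 splits called as many genes (real 385, highest other 2990). The splits with 2990 and 1711 genes part 1 of the 3 pairs, which points to a structure of the samples, and of the 4 splits that part all 3 pairs the others called 0. The real counts and the highest others were 9049 and 0 for FBZ, 7466 and 1 for OxBZ, 259 and 1 for MBZ, with 1 split as large in each, and 1089 and 1187 for TBZ, with 2. For pairs they were 7459 and 0 (ABZ–FBZ), 7602 and 562 (ABZ–OxBZ), 36 and 0 (ABZ–MBZ), 1107 and 69 (ABZ–TBZ), 10488 and 0 (FBZ–OxBZ), 4710 and 0 (FBZ–MBZ), 6249 and 0 (FBZ–TBZ), 7419 and 0 (OxBZ–MBZ) and 7337 and 0 (OxBZ–TBZ), with 1 split as large in each, and 604 and 839 (MBZ–TBZ), with 2. For any difference among the 6 groups, 1 of 60 splits, the real one, called as many as 12154 genes and the highest other 3045. This argues against a random grouping of the libraries as the source of that count. The splits treat all 18 libraries as exchangeable, so they cannot tell a drug effect from cultures shared within a group.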
